A study of Mus musculus with 10 samples.

How the data were processed

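Whole skin RNA was measured in 10 libraries of C57BL/6 mice raised under specific pathogen free conditions, 5 in the SA group (Staphylococcus aureus SF8300) and 5 in the SE group (Staphylococcus epidermidis Tü3298). Per the labels' protocols, 100 µl of bacterial suspension was applied to newborn mice every other day from day 3 to day 19, and an 8 mm punch of back skin was taken at day 21, lightly freed of fat and extracted with a column kit for fibrous tissue. Groups and replicate numbers came from the sample titles. No batch, litter or sex is given in the labels used here.

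The deposited counts are whole-number reads per Ensembl gene, which the authors made with STAR 2.4.2a, SAMtools and HTSeq 0.6.1p1 on GRCm38 (mm10), per the submitters' processing notes. The annotation release, the counting mode and the strand setting are not given in the sources used here. Without a known strand setting, reads of overlapping genes on opposite strands cannot be told apart, and reads of near-identical copies can be lost or shared. The table held 46078 genes, of which 16975 had no read in any library, and 5 rows that name no gene. Those 5 rows were left out of library sizes and tests. Reads with no feature took 3.06% to 6.59% of all listed reads per library, ambiguous reads 3.1% to 3.4% and reads not aligned uniquely 23.1% to 26.7%, which left 65.4% to 69.5% on genes.

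A second deposited table holds the authors' own comparison, made with DESeq2 per the submitters' processing notes. Its group means are normalized counts, a signal that the authors obtained by dividing counts by size factors. Its log2 fold changes, as deposited, were smaller than the log2 ratio of the deposited means, and its p-values and adjusted p-values were taken as deposited. They appear in the text only as the authors' deposited table and entered no test. Gene symbols were taken for 45348 IDs from that table and for 47 more from the GENCODE annotation of GRCm38, and 683 IDs had none. Coordinates came from the same GENCODE annotation.

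Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr defaults (minimum count 10), which left 16909, libraries were scaled with TMM, and the SA and SE groups were compared with the two-sided quasi-likelihood test without covariates. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are log2 SA minus SE with a prior count of 0.125, given with their standard errors, the fold change over the square root of the F statistic, and CPM values, counts per library scaled to the same total, are TMM-scaled and given with SDs over 5 libraries. The biological coefficient of variation was 18%. Gene reads per library lay between 21140654 and 25417851, so that 1 CPM stands for more than 20 reads. Gene-assigned reads, the shares of each read class, mitochondrial reads and the share of the top 10 genes did not differ past the threshold between groups (exact permutation p between 0.222 and 0.96, n = 5 each). Replicates were compared before averaging. The chi-square per degree of freedom of their counts lay between 5.1 and 38.1 for SA pairs and between 14.6 and 83.9 for SE pairs, so no pair agreed within sampling noise.

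Gene lists were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 32 lists with at least 5 tested members. The lists covered the IL-1 family, the NF-kB response, pattern recognition receptors, antimicrobial peptides, keratinocyte stress, terminal differentiation, barrier lipids, basal keratinocytes, hair shaft and inner root sheath, melanocytes, sebaceous gland, fibroblasts, adipocytes, skeletal muscle, endothelium and Schwann cells. They further covered neutrophils, macrophages, dendritic and Langerhans cells, T cells, regulatory T cells, gamma-delta T cells and type 17 genes, natural killer cells, B cells, mast cells, type 2 immunity, both interferon responses, proliferation, immediate early and heat shock genes, the circadian clock and red blood cells. A list of sex-linked genes was described and not tested. A list score is the mean log2 CPM of its tested members in a library, compared by a two-sided exact permutation test over all splits of 5 against 5. Another 5 lists, for fatty acid synthesis, cholesterol synthesis, fasting, glucocorticoid response and alpha-beta T cells, were written after the data were seen and appear only in the closing observations.

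The genes named were set by a rule before the data were examined. It took up to 10 genes per direction past the threshold with a mean CPM of at least 1 and a symbol that is not a predicted-gene name, ordered by fold change. It also took fixed genes whatever their values, among them Il1b, Il1a, Il1rn, Il1r1, Cxcl2, S100a8, S100a9, Lcn2, Tlr2, Il17a and Foxp3, and up to 4 members with the smallest p of each called list. Some genes the rule took are not reported here, and they stayed in every test and list. Maf, Sox13 and Il13ra2, and members of the added lists, fall outside the rule and were named after their values were seen.

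The procedure was tested on simulated counts drawn from the means, dispersions and library sizes of these libraries, with 200 changed genes in each of 3 runs over 16909 genes of the SA against SE comparison. Changed genes were drawn from those with a mean CPM of at least 1, so recovery is not known for lower genes. The edgeR test recovered 37.8% of genes changed by 0.5 on the log2 scale, 86.6% of those changed by 1 and 98% of those changed by 2, with 4.98% false among its calls. DESeq2 recovered 57.7%, 91% and 98%, with 19.3% false among its calls. A shifted list was called in 3 of 3 runs, and 1 of 150 unchanged lists had a p under 0.05. Genes were drawn independently and no library was set apart, so the list rate does not hold for lists whose genes vary together between libraries. The shares of false gene calls likewise need not hold for the real libraries, where some libraries stand apart.

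Alternatives fixed before the data were examined were DESeq2 1.42.0, limma voom, DESeq2 size factors or total counts for scaling, no filter or a filter of CPM 1 in 5 libraries, robust dispersion, the replicate number as a block, the muscle or hair list score as a covariate, 1 surrogate variable from sva 3.50.0, each library left out, a threshold of 0.1 and a minimum log2 fold change of 1. For lists they were an estimated correlation and the fry test. Added after the data were seen were a fit without SE libraries 3, 4 and 5 and a fit with the sex-gene type as a covariate.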

Results

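Whole back skin of C57BL/6 mice was profiled by RNA sequencing after repeated colonisation of newborn animals with 1 of 2 staphylococci. The SA group received Staphylococcus aureus SF8300 and the SE group received Staphylococcus epidermidis Tü3298, a species that commonly lives on healthy skin. Bacteria were applied from day 3 to day 19 of life, skin was taken at day 21, and each group held 5 libraries. The comparison asks how skin gene expression differs between young mice carrying the pathogen and those carrying the commensal. No uncolonised skin was analysed here, so each difference is relative between the groups. Reads assigned to genes ranged from 21140654 to 25417851 per library, which made genes near 1 CPM, the read count scaled to library size, measurable with more than 20 reads. Mean gene-assigned reads were 22690000 ± 1250000 in SA and 22890000 ± 1540000 in SE (SD, n = 5 each, exact permutation p = 0.81). The labels do not say that each library came from a separate mouse, so p-values measure the spread between these libraries.

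Libraries within a group were not alike. SE libraries 3, 4 and 5 stood apart from the other 7 on the first principal component, which held 45.2% of the variance. They lay at 37.9, 41.8 and 54.3 on it, and the other 7 lay between -32.6 and -9.34. Ddx3y, a Y-linked gene, had more reads than Xist, which is expressed from the inactive X chromosome, in 3 libraries, namely SA 1, SA 3 and SE 3. Medians of the called gene lists are given below also without SE libraries 3, 4 and 5, an alternative chosen after the data were seen that leaves 5 SA and 2 SE libraries.

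SA skin had higher transcript levels of gamma-delta T cell genes, interleukin-36 gamma and malic enzyme, and lower levels of neuronatin and of a pair of muscle genes. At an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 13 of 16909 tested genes differed, 10 higher and 3 lower in SA. Regrouping the libraries did not exclude chance for this count, as given in the closing observations. Cd163l1, a scavenger receptor known from gamma-delta T cells, was 5.81-fold higher, at 23.6 ± 3.39 CPM in SA against 4.06 ± 1.53 in SE (SD, n = 5 each, log2 fold change 2.54 ± 0.215, standard error, as after every log2 fold change here, edgeR adjusted p = 0.00102). Tcrg-V6, the variable segment of an invariant gamma-delta T cell receptor found in dermis, rose by 2.92 ± 0.455 on the log2 scale from 0.243 ± 0.254 to 1.84 ± 0.431 CPM (edgeR adjusted p = 0.0455). Nnat, the imprinted gene of neuronatin, was 5.91-fold lower in SA, at 13.1 ± 2.85 against 77.3 ± 28.9 CPM (edgeR adjusted p = 0.00187).

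Another 8 genes were higher and 2 more lower in SA. Blk, a Src-family kinase of B cells and of gamma-delta T cells that make interleukin-17, rose by 1.92 ± 0.213 (adjusted p = 0.00303). Cxcr6, a chemokine receptor of tissue-resident lymphocytes, rose by 1.64 ± 0.155 from 4.47 ± 0.644 to 13.9 ± 2.52 CPM (adjusted p = 0.00178). Trdc, the constant segment of the T cell receptor delta chain, rose by 0.73 ± 0.102 (adjusted p = 0.022). Il1f9, which encodes the epithelial cytokine interleukin-36 gamma, rose by 0.75 ± 0.0823 from 25.7 ± 2.19 to 43.1 ± 3.65 CPM (adjusted p = 0.00303). Me1, the malic enzyme that supplies NADPH for fatty acid synthesis, was the most abundant of the 13 and rose by 0.83 ± 0.0885 from 227 ± 28.2 to 405 ± 17 CPM (adjusted p = 0.00294). The glutathione transferase gene Gsta3 rose by 1.06, the serine protease gene Prss27 by 0.93 and the gelatinase gene Mmp9 by 0.62. Two-sided edgeR adjusted p-values of these last genes were 0.0455, 0.0362 and 0.0362. Among the genes lower in SA, Mylk2, a myosin light chain kinase of skeletal muscle, had a log2 fold change of -1.11 ± 0.147, and Apobec2, a muscle deaminase-family gene, one of -1.03 ± 0.116 (adjusted p = 0.0145 and 0.00303).

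**Figure D1:**
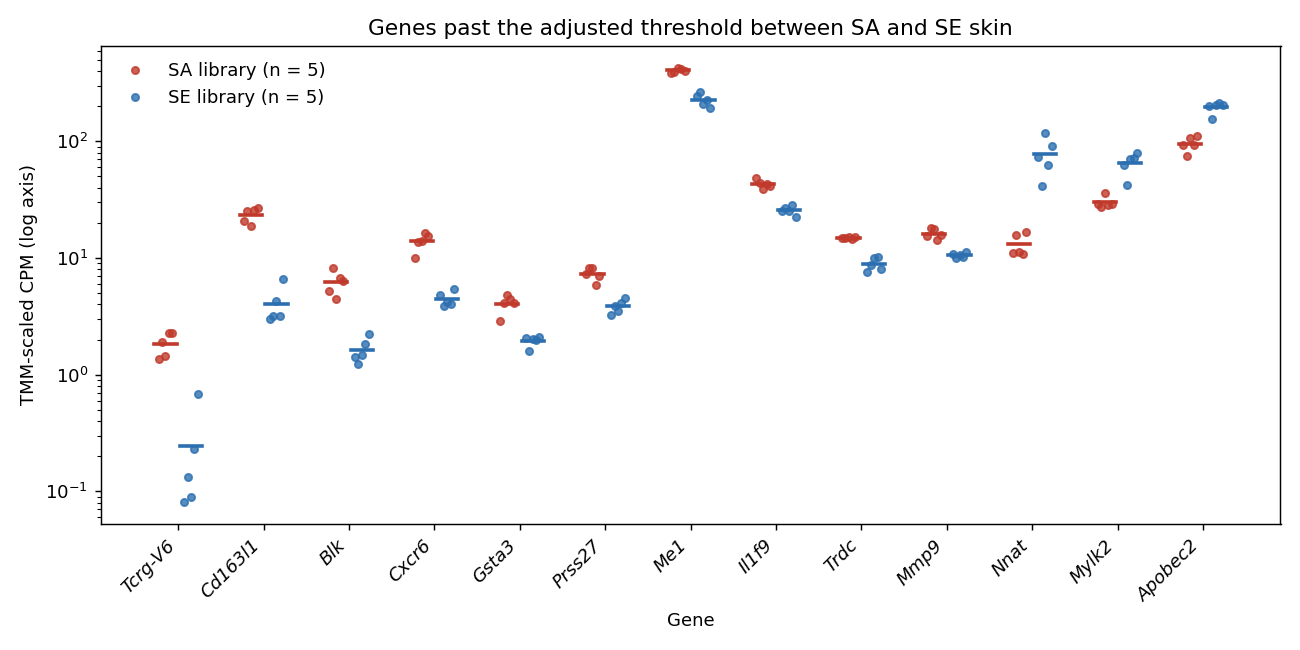
Expression of the 13 genes past the adjusted threshold, as TMM-scaled CPM on a log axis, with 1 point per library and a horizontal bar at the mean of each group of 5. The SA and SE points of each gene do not overlap, from Tcrg-V6 at 1.84 against 0.243 CPM to Me1 at 405 against 227 CPM.

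For each of the 13 genes the 5 SA libraries lay all above or all below the 5 SE libraries. The 13 were picked by a test on these same libraries, so their separation adds no support. It held for 346 of all tested genes, or 2.05%, where chance gives 0.794% on average for exchangeable libraries. Since genes vary together between libraries, the share can lie far from that average without a group effect. Cd163l1 (ENSMUSG00000025461) lies on chromosome 7, 140218267 to 140231145 in GRCm38, and Cxcr6 (ENSMUSG00000048521) on chromosome 9, 123806475 to 123811760. Blk (ENSMUSG00000014453) and Trdc (ENSMUSG00000104876) share chromosome 14, at 63372836 to 63417037 and 54142851 to 54148868. Tcrg-V6 (ENSMUSG00000076746) is annotated as a T cell receptor variable gene on chromosome 13, 19190356 to 19190929. Il1f9 (ENSMUSG00000044103) lies on chromosome 2, 24186476 to 24193568, within the interleukin-1 family cluster that also holds Il1f5, Il1f8 and Il1rn. Nnat (ENSMUSG00000067786) lies on chromosome 2, 157560078 to 157562522, Me1 (ENSMUSG00000032418) on chromosome 9, 86581371 to 86695953, Mylk2 (ENSMUSG00000027470) on chromosome 2, 152911352 to 152923068 and Apobec2 (ENSMUSG00000040694) on chromosome 17, 48419231 to 48432930. Of these genes, Trdc shares 7.84% of its exonic bases with genes on the opposite strand, Nnat 4.76% and Me1 0.78%, and the strand setting of the counting is not given in the sources used here. Some genes named below share more, among them Foxp3 at 31.5%, with genes on both strands. Krt6a shares 24.8%, Alas2 15.5% and Pglyrp2 14.4% with genes on the opposite strand, so their levels are uncertain.

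The number of genes called depended on single SE libraries. Without SE library 1 it was 225, without SE library 2 it was 152, and without any other 1 library it lay between 7 and 11. Cd163l1, Blk, Cxcr6, Me1, Il1f9, Nnat and Apobec2 were called in all 10 of these fits, and the other 6 were not. Tcrg-V6 lost its call without any SA library or without SE 3 or 4 (highest adjusted p = 0.145), and Trdc without any SA library or without SE 5 (0.105). Gsta3 lost it without SA 2, 3, 4 or 5 or SE 3, 4 or 5 (0.146), and Mmp9 without SA 1, 2, 3 or 5 or SE 3, 4 or 5 (0.145). Prss27 lost it without SA 1, 2, 3 or 5 or SE 3 or 4 (0.145), and Mylk2 without SA 1, 2, 4 or 5 (0.086). Without SE libraries 3, 4 and 5 together, 41 genes were called, 27 higher and 14 lower in SA, and 9 of the 13 were among them. Mmp9, Prss27, Gsta3 and Mylk2 were not, at adjusted p of 0.105, 0.0604, 0.129 and 0.0709. Calls were also lost with the replicate block (Tcrg-V6, Trdc, Gsta3, Prss27, Mmp9 and Me1), the hair covariate (Trdc, Gsta3, Prss27, Mmp9 and Mylk2), the sex-gene covariate (Trdc, Gsta3, Prss27 and Mmp9) and limma voom (Gsta3). Over all alternatives the highest adjusted p was 0.278 for each of Mmp9, Prss27 and Gsta3, 0.267 for Trdc, 0.145 for Tcrg-V6, 0.119 for Mylk2 and 0.066 for Me1. DESeq2 called 341 genes, 143 higher and 198 lower, which included all 13.

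The authors' deposited table, which per the labels came from DESeq2, holds 215 genes at an adjusted p under 0.05. Of these, 119 were higher in SA and 96 lower, and all 13 genes above were called there with the same sign. Of the 215, 206 were tested here with edgeR, and each of those 206 had the same sign with an unadjusted p under 0.05.

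Gene lists were fixed before the data were examined, and 22 of 32 were called by camera with a preset correlation of 0.01. Of these, 20 were higher and 2 lower in SA. Chance was not excluded for this count of lists either, as given in the closing observations. With an estimated inter-gene correlation 5 calls held, namely those of the gamma-delta T cell and type 17, T cell, IL-1 family, neutrophil and sebaceous gland lists. Library scores, the mean log2 CPM of a list's members, did not overlap between groups for these 5 lists and for the B cell list (exact permutation p = 0.00794, adjusted over 32 lists 0.0423, n = 5 each). Ranges over all alternatives cover 19 fits per list. The neutrophil and B cell lists have 18, since the stricter low-count filter left them under 5 tested members.

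Gamma-delta T cell and type 17 genes were higher in SA skin, with a median log2 fold change of 0.71 over 13 measured members (camera adjusted p = 5.43e-13, 0.0196 with an estimated correlation, range 1.87e-17 to 0.0196 over all alternatives). Over all genes 3 members rose, namely Blk, Trdc and Tcrg-V6. Adjusted over the list alone 8 rose and 2 fell, the latter being the transcription factor genes Maf at -0.25 and Sox13 at -0.29, which are named here because of their values. Il23r, the receptor for interleukin-23, had a log2 fold change of 1.86 ± 0.322 and missed the threshold over all genes (edgeR adjusted p = 0.0726). The list score was 2.88 ± 0.123 in SA and 2.13 ± 0.221 in SE (SD, n = 5 each). Il17a was under the expression filter, with 13 reads in all SA libraries together and 5 in all SE libraries. The list kept its call without SE libraries 3, 4 and 5, at a median of 0.83.

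T cell genes were also higher, with 13 of 14 members positive and a median of 0.38 (camera adjusted p = 1.23e-08, 0.0176 with an estimated correlation, range 4.34e-10 to 0.0176 over all alternatives). No member passed over all genes, and 6 rose adjusted over the list alone. Cd3d, part of the T cell receptor complex, had 0.77 ± 0.152, the adaptor gene Lat 0.80 ± 0.18 and the kinase gene Zap70 0.77 ± 0.167 (edgeR adjusted p = 0.0951 for Cd3d and 0.14 for Lat). These genes also serve gamma-delta T cells. The list median was 0.28 without SE libraries 3, 4 and 5. Regulatory T cell genes were called at a median of 0.13 (camera adjusted p = 0.00465, 0.113 with an estimated correlation, range 0.000236 to 0.113 over all alternatives), with 2 of 12 members higher adjusted over the list alone, Icos at 0.78 and Ikzf4 at 0.68. Their median was 0.26 without SE libraries 3, 4 and 5, and the call was lost without SE library 2 (adjusted p = 0.0626). Foxp3, their lineage factor, was low at 0.517 ± 0.314 CPM in SA and 0.565 ± 0.0831 in SE and did not differ past the threshold (-0.12 ± 0.405, edgeR adjusted p = 0.921).

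Interleukin-1 family genes were higher in SA, with 19 of 24 members positive and a median of 0.15 (camera adjusted p = 1.11e-07, 0.0176 with an estimated correlation, range 3.24e-09 to 0.0176 over all alternatives). The median fell to 0.09 without SE libraries 3, 4 and 5, and the list stayed called. Il1f9 rose over all genes, and 6 members rose adjusted over the list alone. Besides Il1f9, the interleukin-36 genes Il1f8, at 0.78 ± 0.137, and Il1f5, which encodes the interleukin-36 receptor antagonist, at 0.36 ± 0.0934, were among them, as was Il18r1 at 0.75 ± 0.164. Over all genes their edgeR adjusted p was 0.0726, 0.175 and 0.128. Il1b, also higher adjusted over the list alone, had 1.64 ± 0.445 with 4.07 ± 3.18 CPM in SA and 1.3 ± 0.412 in SE, and it missed the threshold in edgeR (adjusted p = 0.201) and passed it in DESeq2 (adjusted p = 0.0127), with a range of 0.0127 to 0.577 over all alternatives. SA library 4 had the highest Il1b level, at 9.57 CPM, and the other 4 SA libraries had at most 3.69 CPM. Il1a (0.17 ± 0.178), the antagonist gene Il1rn (0.01 ± 0.095) and the receptor gene Il1r1 (-0.11 ± 0.0696) did not differ past the threshold. Without SE libraries 3, 4 and 5, Il1a was at 0.63 ± 0.153 and still missed it (edgeR adjusted p = 0.173).

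Neutrophil genes were higher, at a median of 0.78 over the 7 measured members (camera adjusted p = 1.29e-05, 0.0176 with an estimated correlation, range 1.10e-06 to 0.0176 over 18 alternatives). Mmp9 rose over all genes. Adjusted over the list alone 4 members rose, among them the granulocyte growth factor receptor gene Csf3r at 0.78 ± 0.236, the chemokine receptor gene Cxcr2 at 0.81 ± 0.316 and the collagenase gene Mmp8 at 0.83 ± 0.313. All 3 were low, at 4.8 ± 1.47, 1.94 ± 0.722 and 0.776 ± 0.152 CPM in SA. Of the 7 measured members, 5 were positive and 2 negative. Beyond these 7, the rest of the 15 genes of this list were under the expression filter. Summed over the SA and the SE libraries, Ly6g had 1 and 0 reads, Mpo 15 and 13, Elane 10 and 3 and Retnlg 59 and 34. The neutrophil median was 0.69 without SE libraries 3, 4 and 5. B cell genes were called at a median of 0.18 over 5 members (camera adjusted p = 0.0401, 0.159 with an estimated correlation, range 0.015 to 0.235 over 18 alternatives), with Ighm at 0.80 and Cd79b at 0.76 higher adjusted over the list alone, Ighd at 0.18 and Ms4a1 at -0.09. The B cell median was 0.69 without SE libraries 3, 4 and 5, while Ighm fell to 0.32, Cd79b was at 0.82 and Ighd rose to 0.69. The B cell call was lost without SA library 2, SA library 5 or SE library 2 (adjusted p = 0.0512, 0.102 and 0.235).

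Antimicrobial and innate response genes were called higher as 3 lists with the preset correlation, and none of these calls held with an estimated one. Antimicrobial peptide genes had a median of 0.23 (camera adjusted p = 0.00555, 0.0852 with an estimated correlation, range 1.97e-06 to 0.0852 over all alternatives), and 2 of 13 members rose adjusted over the list alone. These were S100a8 at 1.65 ± 0.494 and S100a9 at 1.47 ± 0.409, the subunits of calprotectin, with edgeR adjusted p over all genes of 0.261 and 0.215. S100a8 reached 13.9 ± 8.94 CPM in SA and 4.43 ± 2.98 in SE. Lcn2, which encodes a siderophore-binding protein, had 0.76 ± 0.351 (adjusted p = 0.453), and Pglyrp2 had 0.89 ± 0.358. S100a7a went the other way at -2.51 ± 0.873, and its sign turned to 0.88 without SE libraries 3, 4 and 5. The antimicrobial list had a median of 0.55 without those 3 libraries, and it lost its call without SE library 1 (adjusted p = 0.0606). The NF-kB response list had a median of 0.12, and 2 of 12 members rose adjusted over the list alone, Zc3h12a at 0.58 ± 0.114 and the acute phase gene Saa3 at 3.12 ± 0.792 (camera adjusted p = 0.00733, 0.254 with an estimated correlation, range 0.000537 to 0.254 over all alternatives). That call was lost without SA library 2 or SE library 1 (adjusted p = 0.106 and 0.0576) and without SE libraries 3, 4 and 5 (median 0.15, adjusted p = 0.183). Saa3 had 1.54 CPM in SE library 2 and at most 0.137 in the other 4 SE libraries, and its log2 fold change was 5.03 without that library (adjusted p = 0.022, range 0.022 to 0.552 over all alternatives). Ccl20 in that list had 0.59 ± 0.331 and Ptgs2 0.43 ± 0.262. Cxcl2 was under the expression filter, with 107 reads in SA library 4 and 1 to 6 reads in each of the other 9 libraries. Pattern recognition receptor genes had a median of 0.25 (camera adjusted p = 0.00192, 0.357 with an estimated correlation, range 4.97e-07 to 0.357 over all alternatives), with Ifih1 at 0.26 and Clec4n at 0.55 higher adjusted over the list alone, Tlr6 at 0.51 and Tlr2 at 0.27 ± 0.226 (adjusted p = 0.666). The receptor median was 0.26 without SE libraries 3, 4 and 5, and the call was lost without SE library 2 (adjusted p = 0.101).

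**Figure D2:**
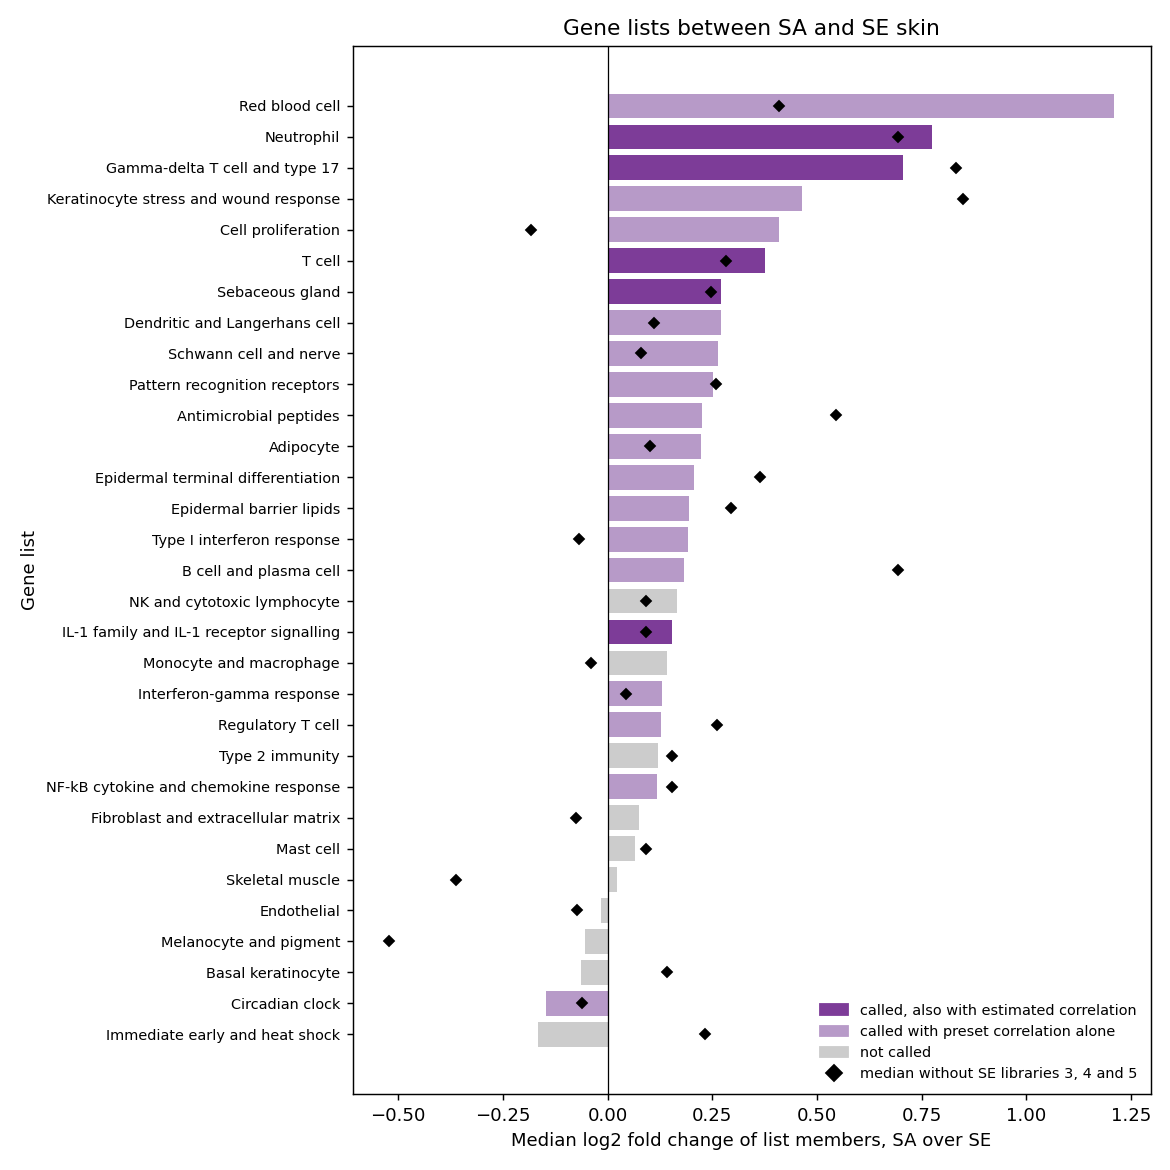
Median log2 fold change of the members of 31 gene lists, SA over SE, as bars coloured by whether camera called the list with a preset and with an estimated correlation, and as diamonds without SE libraries 3, 4 and 5. The hair shaft list, at -4.58, is left out because it would set the scale. The gamma-delta T cell bar stands at 0.71 with its diamond at 0.83, and cell proliferation moves from 0.41 to -0.18.

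Gene lists of the outer epidermis and the sebaceous gland were called higher in SA with the preset correlation, and of these calls the sebaceous one alone held with an estimated correlation. Sebaceous gland genes had a median of 0.27, with 13 of 15 members positive (camera adjusted p = 6.56e-08, 0.0408 with an estimated correlation, range 1.98e-10 to 0.0408 over all alternatives). Scd1, a desaturase of sebum lipids, was among the most abundant at 4248 ± 220 against 2776 ± 507 CPM (0.61 ± 0.127, edgeR adjusted p = 0.108). Adjusted over the list alone 4 members rose, which were Scd1, Plin2 at 0.30 ± 0.0768, Elovl3 at 0.74 ± 0.233 and Far2 at 0.27 ± 0.0917. Scd1 was at 0.37, Elovl3 at 0.26, the sebaceous median at 0.25 and the barrier lipid median at 0.29 without SE libraries 3, 4 and 5. Barrier lipid genes had a median of 0.20 over all libraries, with 15 of 16 members positive and 5 higher adjusted over the list alone (camera adjusted p = 8.86e-08, 0.0917 with an estimated correlation, range 6.64e-11 to 0.0917 over all alternatives), led by the acyltransferase gene Dgat2 at 0.63 ± 0.107, Sdr9c7 at 0.38 ± 0.0895, the lipoxygenase gene Alox12b at 0.35 ± 0.0958 and Smpd1 at 0.26 ± 0.0753. Terminal differentiation genes had a median of 0.21 (camera adjusted p = 5.29e-07, 0.271 with an estimated correlation, range 1.79e-16 to 0.271 over all alternatives). Ivl, which encodes the cornified envelope protein involucrin, was the 1 of 31 members that rose adjusted over the list alone (0.51 ± 0.0867), with Hrnr at 0.47, Lce1e at 0.66 and Lce1h at 0.61. The median of this list was 0.36 without SE libraries 3, 4 and 5. Keratinocyte stress genes moved in both directions. Krt6b at 2.34 ± 0.564, Sprr1b at 1.56 ± 0.426 and Sprr2d at 2.08 ± 0.597 rose and Krt6a at -1.42 ± 0.471 fell adjusted over the list alone, with a list median of 0.46 (camera adjusted p = 0.00136, 0.115 with an estimated correlation, range 1.34e-08 to 0.116 over all alternatives). The stress list lost its call without SE library 1 (adjusted p = 0.116). Its median was 0.85 without SE libraries 3, 4 and 5, and Krt6a then turned to 0.38. Near-identical family members, such as Krt6a and Krt6b or the Sprr2 and Lce1 genes, can share reads, and their single values are uncertain.

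Hair shaft and inner root sheath genes were lower in the SA group as a whole and high in 3 SE libraries. The list median was -4.58, with 25 of 26 members negative and 22 lower adjusted over the list alone (camera adjusted p = 3.02e-16, 0.172 with an estimated correlation, range 6.90e-25 to 0.89 over all alternatives). The 0.89 came from the hair covariate, which is the score of this same list, so that fit could not test it. List scores were 4.2, 3.64 and 5.63 in SE libraries 3, 4 and 5, -0.0864 and 1.31 in SE libraries 1 and 2, and between -0.347 and 1.18 in the SA libraries. Krt27, a keratin of the inner root sheath, averaged 1.99 ± 1.88 CPM in SA and 117 ± 167 in SE (edgeR adjusted p = 0.121), and Krtap8-1, Krt84 and Krt36 had log2 fold changes of -6.30, -5.74 and -5.23. The median was -0.15 without SE libraries 3, 4 and 5, and the list was then not called (adjusted p = 0.495).

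Cell proliferation genes moved with the same 3 libraries. All 22 members were positive, with a median of 0.41 (camera adjusted p = 8.39e-08, 0.349 with an estimated correlation, range 1.89e-15 to 0.349 over all alternatives), and none passed adjusted over the list alone. Scores were 3.99, 4.17 and 4.01 in SE libraries 3, 4 and 5 and between 4.82 and 5.38 in the other 7. The mitotic genes Cdc20, Tpx2, Plk1 and Kif11 had log2 fold changes of 0.58, 0.53, 0.59 and 0.46. The direction turned without SE libraries 3, 4 and 5, at a median of -0.18 (camera adjusted p = 0.000299).

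**Figure D3:**
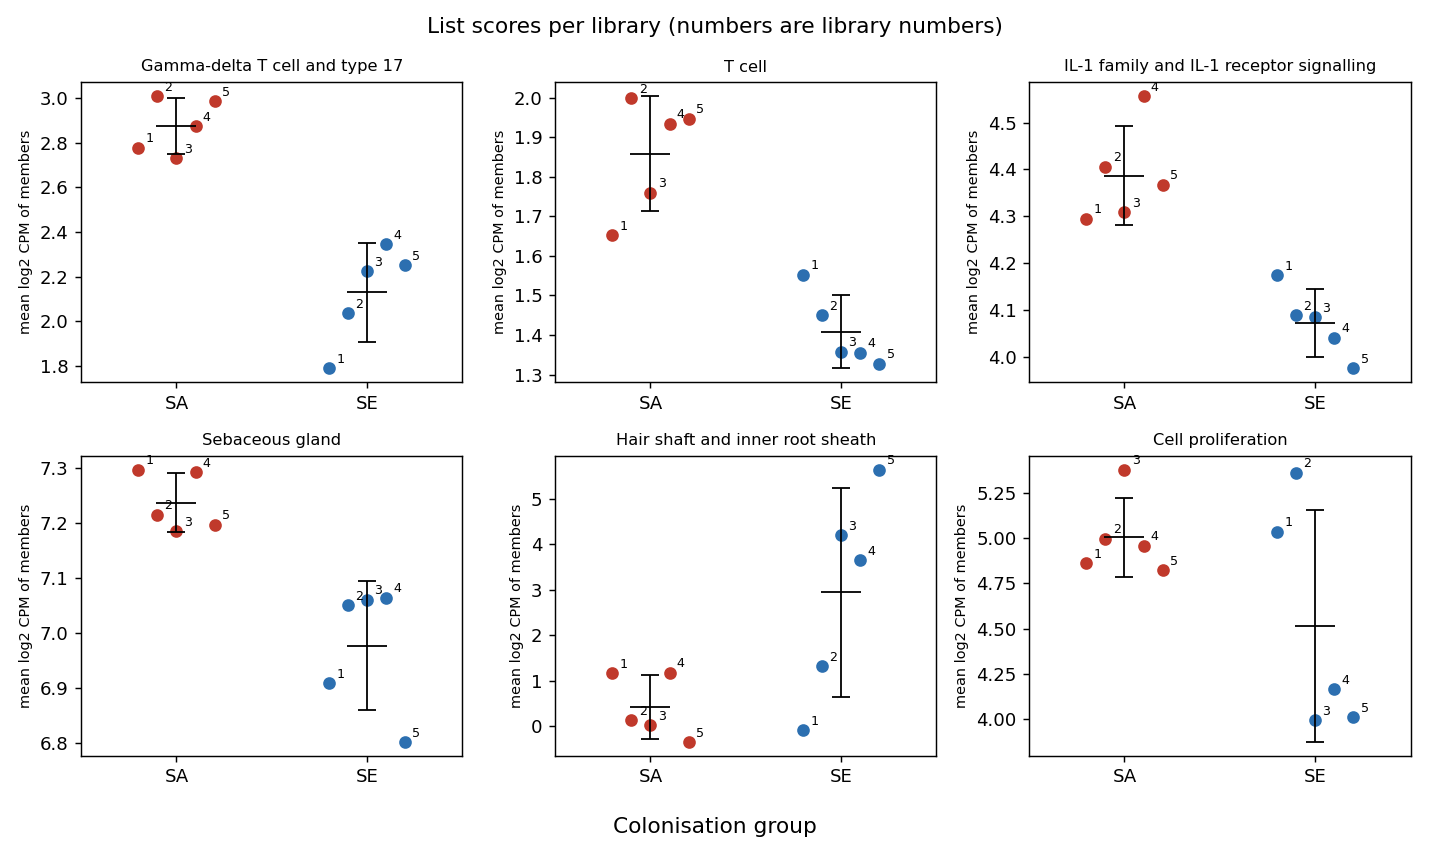
Scores of 6 gene lists, as the mean log2 CPM of their members, with 1 numbered point per library and the mean and SD of each group of 5 as a horizontal mark with bars. The SA and SE points are apart in the gamma-delta T cell, T cell, IL-1 and sebaceous panels, while SE libraries 3, 4 and 5 lie apart from SE libraries 1 and 2 in the hair shaft and proliferation panels.

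Other called lists kept the sign of their median without these 3 libraries, apart from the type I interferon list, and several were no longer called. Red blood cell genes had a median of 1.21 (camera adjusted p = 1.74e-07, 0.0917 with an estimated correlation, range 8.26e-16 to 0.0917 over all alternatives), and 6 of 7 members rose adjusted over the list alone. Hba-a1 averaged 57.4 ± 13.1 CPM in SA and 24.7 ± 19.6 in SE, with its near-identical copy Hba-a2 at 1.22 and Alas2 at 0.98. Without the 3 libraries the median was 0.41. Adipocyte genes had a median of 0.22 with 3 members higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000523, 0.357 with an estimated correlation, range 1.48e-07 to 0.357 over all alternatives). The members that rose were the fatty acid synthesis genes Fasn at 1.20 ± 0.232 and Acaca at 0.92 ± 0.175 and the adipokine gene Retn at 0.88, and the lipid droplet gene Plin4 fell at -0.63. These 4 values were 0.71, 0.60, 0.36 and -0.59 without the 3 libraries. Dendritic and Langerhans cell genes had a median of 0.27 (camera adjusted p = 8.12e-06, 0.271 with an estimated correlation, range 1.71e-09 to 0.404 over all alternatives), with the Langerhans cell gene Cd207 at 0.29 ± 0.0735 higher adjusted over the list alone, Cd209a at 0.77, H2-DMa at 0.33 and Ccr7 at 0.74. Schwann cell and nerve genes had a median of 0.27 with no member past the threshold of the list (camera adjusted p = 0.00112, 0.271 with an estimated correlation, range 1.04e-05 to 0.58 over all alternatives), Sox2 at 0.62, Mag at 0.41 and Prx at 0.33. Without the 3 libraries the medians were 0.10 for adipocyte, 0.11 for dendritic cell and 0.08 for Schwann cell genes, and none was called (adjusted p = 0.0868, 0.145 and 0.58).

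Interferon lists were called with the preset correlation and had no member past the threshold of their list. Type I interferon response genes had 20 of 22 members positive at a median of 0.19 (camera adjusted p = 0.000137, 0.357 with an estimated correlation, range 5.38e-10 to 0.357 over all alternatives), with Rsad2 at 0.55, Xaf1 at 0.29 and Ifit3b at 0.57. Interferon-gamma response genes had a median of 0.13 (camera adjusted p = 0.0217, 0.357 with an estimated correlation, range 0.000341 to 0.89 over all alternatives), with Psmb9 at 0.27, Nos2 at 0.32, Cxcl9 at 0.30 and Gbp4 at -0.16. The interferon-gamma call was lost without SA library 2, 4 or 5 or SE library 2 (adjusted p = 0.0618, 0.0553, 0.062 and 0.0899). The medians were -0.07 and 0.04 without SE libraries 3, 4 and 5, and neither list was called (adjusted p = 0.144 and 0.575). Circadian clock genes were lower in SA at a median of -0.15 (camera adjusted p = 0.0125, 0.271 with an estimated correlation, range 0.00184 to 0.271 over all alternatives), with Per2 at -1.03 ± 0.342, Ciart at -0.53, Tef at -0.25 and Cry1 at -0.26. That call was lost without SA library 3, SE library 2 or SE libraries 3, 4 and 5 (adjusted p = 0.0554, 0.0899 and 0.098), where in the last case the median was -0.06.

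Of the 32 lists, 10 were not called, which does not show that their cells were equally frequent. Camera adjusted p was 0.209 for basal keratinocyte, 0.628 for melanocyte, 0.595 for fibroblast, 0.504 for endothelial, 0.209 for macrophage, 0.229 for natural killer cell and 0.619 for mast cell genes. It was 0.102 for type 2 immunity, 0.0852 for immediate early and heat shock, and 0.9 for skeletal muscle genes. No member of these lists passed over all genes, and 1, the type 2 receptor gene Il13ra2 at 0.82 ± 0.19, was higher adjusted over the list alone. The muscle list had a median of 0.02 and a mean of 0.00364, both positive, while its test direction was negative. Without SA library 1, basal keratinocyte and immediate early lists were called lower in SA and fibroblast, mast cell, macrophage and type 2 immunity lists higher (adjusted p = 0.0181, 0.00886, 0.00426, 0.044, 0.00503 and 0.011). Without SE library 1, the same lists except mast cell were called in the same directions (adjusted p = 0.00896, 0.000175, 0.028, 0.00229 and 0.0434), and immediate early genes were called lower also without SA library 2 and with the sex-gene covariate (adjusted p = 0.00844 and 0.0218). Without SE libraries 3, 4 and 5, melanocyte genes at a median of -0.52 and muscle genes at -0.36 were called lower in SA, while basal keratinocyte genes at 0.14 and immediate early genes at 0.23 were called higher (adjusted p = 0.000115, 4.05e-09, 0.0193 and 0.0241). The basal keratinocyte and immediate early lists were thus called in opposite directions depending on the libraries left out. The hair covariate called the same 4 lists in the same directions as the fit without these 3 libraries, and fibroblast genes lower (adjusted p = 0.00356, 2.00e-05, 0.0414, 0.0199 and 0.0444). Over all alternatives, adjusted p of the 10 lists lay between 4.05e-09 and 0.994.

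Single genes named above also moved with SE libraries 3, 4 and 5. Besides those given with their list, log2 fold changes of genes named by the rule that fell by a factor of over 1.5 without these libraries were then Lcn2 at 0.25, Tlr2 at 0.03, Foxp3 at -0.08, Saa3 at 2.06, Sprr2d at 1.13, Hrnr at 0.29, Dgat2 at 0.41, Krt27 at -1.49, Krt36 at -0.18, Krtap8-1 at -0.10, Mag at 0.19, Prx at 0.15, Cd209a at 0.36, H2-DMa at 0.14, Ccr4 at 0.29, Xaf1 at 0.17, Ifit3b at 0.23, Psmb9 at 0.06, Cxcl9 at 0.09, Per2 at -0.60, Ciart at -0.29, Cry1 at -0.00363, Hba-a2 at 0.41, Hba-a1 at 0.39 and Alas2 at 0.34. Those that grew by a factor of over 1.5, besides those given with their list, were Ccl20, Mmp8, Cxcr2, Ccr7 and Il1rn. Of these, Mmp8 was then at 1.29, Cxcr2 at 1.27, Ccr7 at 1.14 and Il1rn at 0.07. Those that changed sign were Krt84 at 0.40, Ms4a1 at 0.14, Nos2 at -0.02, Gbp4 at 0.05, Cdc20 at -0.02, Tpx2 at -0.04, Plk1 at -0.04 and Kif11 at -0.09.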

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

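Single libraries that lay far from the other 4 of their group were looked for with Dixon's ratio, the gap to the nearest library over the range of the group, with a critical value of 0.71 for 5 libraries. Of 290 groups examined, 29 passed, where chance passes about 5%. Each is given as its ratio and the value of the library against the range of the other 4.

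Among genes that differed past the threshold, this applied to Tcrg-V6 in SE library 5 (0.755, 0.685 against 0.081 to 0.229 CPM), Gsta3 in SE library 2 (0.744, 1.58 against 1.97 to 2.1 CPM), Mylk2 in SA library 3 (0.774, 36.2 against 27.3 to 29.3 CPM) and Apobec2 in SE library 2 (0.781, 154 against 201 to 214 CPM). Among inflammatory and antimicrobial genes it applied to Il1b in SA library 4 (0.752, 9.57 against 1.75 to 3.69 CPM), Lcn2 in SE library 2 (0.793, 6.72 against 2.11 to 3.06 CPM), Saa3 in SE library 2 (0.939, 1.54 against 0.046 to 0.137 CPM), S100a7a in SE library 5 (0.734, 22 against 0.322 to 6.1 CPM) and Mmp8 in SE library 5 (0.819, 0.823 against 0.308 to 0.401 CPM). Read counts did so for Cxcl2 in SA library 4 (0.971, 107 against 3 to 6 reads) and Il17a in SE library 1 (0.75, 4 against 0 to 1 reads).

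Hair genes stood out in SE library 5, namely Krt27 in SE library 5 (0.719, 405 against 2.3 to 115 CPM), Krtap8-1 in SE library 5 (0.74, 163 against 0.282 to 42.5 CPM) and Krt84 in SE library 5 (0.766, 125 against 0.04 to 29.2 CPM). Prx, a myelin gene, did so in SA library 2 (0.752, 103 against 61.7 to 71.9 CPM). In SE library 1, further genes stood out, namely H2-DMa in SE library 1 (0.826, 46 against 29.1 to 32 CPM), Zap70 in SE library 1 (0.721, 1.29 against 1.79 to 1.98 CPM), Ighm in SE library 1 (0.735, 83.4 against 27.2 to 42.1 CPM) and Alas2 in SE library 1 (0.783, 21.6 against 4.45 to 8.17 CPM). The remaining genes were Xaf1 in SE library 2 (0.766, 9.19 against 7.08 to 7.57 CPM), Cxcl9 in SA library 1 (0.79, 2.53 against 3.92 to 4.29 CPM) and Cdc20 in SA library 3 (0.727, 31.4 against 20.6 to 23.6 CPM).

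Several list scores were low in SA library 1, namely dendritic cell genes in SA library 1 (0.79, 3.85 against 4.27 to 4.38), fibroblast genes in SA library 1 (0.781, 9.48 against 10.1 to 10.3), interferon-gamma response genes in SA library 1 (0.938, 3.34 against 3.67 to 3.69), macrophage genes in SA library 1 (0.806, 4.62 against 5.17 to 5.31) and pattern recognition receptors in SA library 1 (0.725, 3 against 3.43 to 3.59). The same library had the highest mitochondrial share of gene reads of the SA group (0.943, 3.46% against 2.59% to 2.64%). The interferon-gamma response score was high in SE library 1 (0.718, 3.67 against 3.37 to 3.46).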

How the results depend on the processing

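The fits without SE libraries 3, 4 and 5 and with the sex-gene covariate were chosen after the data were seen, and the other alternatives were fixed before. Over all alternatives, 100 results for genes gave 2291 values, of which 2120 kept direction and side of the threshold, 57 kept the direction and lost the call, 88 gained one and 26 reversed, and 88 of the 100 never reversed. The lists fixed beforehand gave 606 values, of which 507 kept both, 55 lost a call, 17 gained one and 27 reversed, and 20 of the 32 lists never reversed. Cd163l1, Blk, Cxcr6, Il1f9, Nnat and Apobec2 kept their calls under each of 23 alternatives (highest adjusted p = 0.0488), and Me1 lost its call in 1, the fit with the replicate block (0.066).

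The 13 called genes (10 higher, 3 lower) became 341 with DESeq2 (143 higher, 198 lower), 142 with the muscle covariate (81 and 61), 76 with 1 surrogate variable (38 and 38), 41 without SE libraries 3, 4 and 5 (27 and 14) and 63 at an adjusted p under 0.1 (43 and 20). With a log2 fold change of at least 1, 8 remained, 5 of them higher. Without a low-count filter 19 were called, 6 of them lower. The hair covariate gave 10 (6 higher, 8 shared with the 13) and the sex-gene covariate 10 (6 higher, 9 shared). With limma voom 12 of the 13 were called, with DESeq2 size factors, the stricter filter or robust dispersion 13, and with total counts 15, 12 of them higher. The median log2 fold change of all genes was -0.00802 with TMM, -0.00887 with size factors and 0.00325 with total counts. Leaving out 1 library at a time gave 7 to 225 genes, 5 to 99 higher and 2 to 126 lower. Called lists went from 22 to 5 with an estimated correlation and to 10 with fry, and lay between 17 and 28 with 1 library left out. With the stricter filter 20 of 30 lists were called, since the neutrophil and B cell lists had under 5 tested members there.

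The labels do not say that the shared numbers 1 to 5 pair the samples, and they were not treated as pairs. Deviations of same-numbered libraries correlated at -0.262, -0.288, -0.13, -0.111 and 0.0715. These values give no sign of pairs but cannot show whether such libraries shared a litter or cage. With the replicate block, 10 genes were called, 4 higher and 6 lower, 7 of them among the 13. The same 22 lists were called with the block.

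Log2 fold changes of genes that did not pass over all genes reversed as follows. With the hair covariate they were 1.16 for S100a7a, 0.281 for Krt6a, 0.0397 for Krt84, 0.142 for Ms4a1, -0.0319 for Nos2, 0.00861 for Gbp4, -0.000916 for Tpx2 and -0.0518 for Kif11. Krt84 is a member of the hair list whose score is that covariate. With 1 surrogate variable they were 0.303 for S100a7a and 0.0929 for Ms4a1. Without SE libraries 3, 4 and 5 they were 0.881 for S100a7a, 0.381 for Krt6a, 0.401 for Krt84, 0.139 for Ms4a1, -0.0154 for Nos2, 0.0458 for Gbp4, -0.0247 for Cdc20, -0.0403 for Tpx2, -0.0407 for Plk1 and -0.0863 for Kif11. With 1 library left out, Il1rn ranged from -0.0633 to 0.0591, Foxp3 from -0.358 to 0.124 and Ms4a1 from -0.172 to 0.00950.

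List directions reversed with the hair covariate for basal keratinocyte (adjusted p = 0.0414), hair shaft (0.89), fibroblast (0.0444), macrophage (0.718), type 2 immunity (0.983), type I interferon (0.256), interferon-gamma (0.89), proliferation (0.0825) and immediate early genes (0.0199). That covariate is the hair list's own score, so the result for the hair list itself was set by the fit and tests nothing. Without SE libraries 3, 4 and 5 they reversed for basal keratinocyte (0.0193), fibroblast (0.149), type I interferon (0.144), proliferation (0.000299), immediate early (0.0241) and, among the lists added later, cholesterol synthesis genes (0.766). Muscle genes reversed with the replicate block (0.994) and the muscle covariate (0.805), which is the muscle list's own score. With 1 library left out, adjusted p ranged from 0.00896 to 0.751 for basal keratinocyte, 0.135 to 0.808 for melanocyte, 0.00426 to 0.849 for fibroblast, 0.0922 to 0.877 for muscle and 0.044 to 0.986 for mast cell genes, each with reversals. The cause was not tested for any of these changes. Genes with few reads, such as Il17a and Cxcl2, were left out of the main test by the low-count filter.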

Other observations

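The lists and tests in this part were chosen after the data were seen, and their p-values are not independent evidence. Fatty acid synthesis genes were higher in SA skin, with 14 of 15 members positive, a median log2 fold change of 0.76 and 11 members higher adjusted over the list alone (camera adjusted p = 1.56e-28, 0.0125 with an estimated correlation). Fasn, fatty acid synthase, stood at 1525 ± 168 CPM in SA and 663 ± 280 in SE (SD, n = 5 each), Acly, which makes acetyl-CoA from citrate, at 564 ± 59.3 and 369 ± 59.1, and Acss2, which makes it from acetate, at 105 ± 6.5 and 54.3 ± 16.2. All 16 cholesterol synthesis genes were positive at a median of 0.33 (adjusted p = 1.12e-09, 0.122 with an estimated correlation), and the direction turned without SE libraries 3, 4 and 5 (adjusted p = 0.766). Alpha-beta T cell genes had a median of 0.14 and were not called (adjusted p = 0.0984).

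Genes of fasting and fatty acid oxidation, at a median of -0.26, and of the glucocorticoid response, at -0.57, were lower in the SA group (adjusted p = 8.2e-13 and 1.12e-09, 0.0446 and 0.0425 with an estimated correlation). Without SE libraries 3, 4 and 5 neither was called (adjusted p = 0.161 for each). Pdk4, which restrains glucose oxidation, was at 22, 29.9, 136, 144 and 114 CPM in SE libraries 1 to 5 and at 14.1 ± 3.25 CPM in SA (SD, n = 5).

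The first pattern was the higher level of gamma-delta T cell and type 17 genes in SA skin. The state of SE libraries 3, 4 and 5 does not account for it, since the median was 0.832 without them against 0.706 with them, and the higher score of SE libraries 1 and 2 was 2.04 against 2.73 for the lowest SA library. The gamma-delta score minus the alpha-beta T cell score was 0.532 higher in SA, at 1.13 ± 0.208 against 0.595 ± 0.293 (SD, n = 5 each, two-sided exact permutation p = 0.00794). Alpha-beta genes thus differed by less, though all 5 were positive. The gamma-delta list was singled out for its rise and the alpha-beta genes were picked after the data were seen. This difference therefore cannot exclude a rise of T cells of every kind. Cell number and RNA per cell were not measured, and litter, cage and the colonising species stay open and were not tested.

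The second pattern was the high level of hair, fasting and glucocorticoid genes in SE libraries 3, 4 and 5. Sex as read from Ddx3y and Xist is argued against by the mix within these libraries. SE library 3 had more Ddx3y than Xist reads, and SE libraries 4 and 5 had fewer. It is also argued against by SA libraries 1 and 3, with hair scores of at most 1.16 against 3.64 for the lowest of the 3 SE libraries. Hair matter left in the biopsies, litter, feeding state, the timing of the hair cycle and a response to S. epidermidis that varies between animals stay open and were not tested.

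The third pattern was the higher level of fatty acid synthesis genes in SA skin. The state of SE libraries 3, 4 and 5 may carry part of it, since the median was 0.398 without them against 0.762 with them. The higher score of SE libraries 1 and 2 was 7.73 against 7.94 for the lowest SA library. This list was written after the data were seen and only 2 SE libraries remain. The gap therefore cannot show that the state of the others is not the whole source. More fat tissue in the SA biopsies as the whole source was set against the adipocyte list, which was fixed before the data were examined. Of its 15 members, 11 had a log2 fold change more than 2 standard errors under 0.762. That median comes from a list written after the data were seen, so the count cannot decide the question. The adipocyte list was itself higher in SA at a median of 0.22, with 11 members positive and 4 negative. Its members Fasn at 1.20 and Acaca at 0.92 also belong to the fatty acid synthesis list, so its rise is in part the pattern itself. More fat tissue may carry part or all of the pattern. Feeding state, sebaceous activity and the colonising species stay open and were not tested.

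Of 126 possible splits of the 10 libraries into 5 and 5, 100 were drawn, the real one included. For genes, 3 of the 100 splits gave 13 or more calls, a share under 0.05, although the highest other split gave 2079. That split set SA libraries 1, 3 and 4 and SE libraries 1 and 2 against the rest, which kept SE libraries 3, 4 and 5 together and points to a structure of the samples. Of the 15 other drawn splits that kept those 3 libraries together, as the real one does, 2 gave 13 or more calls. Chance was thus not excluded for the genes, since the share over all splits treats the libraries as exchangeable. For lists, 5 of the 100 splits gave 22 or more calls with a highest other of 26 and a median of 12 over the other splits, and for DESeq2 10 of the 100 gave 341 or more with a highest other of 3508, so chance was not excluded for either count.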
